A study of Mus musculus with 13 samples.

How the data were processed

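Gene expression was measured on 13 two-colour microarrays, each carrying one sample labelled with Cy3 and a common reference labelled with Cy5, per the labels. The samples were T cells of 5C.C7 T cell receptor transgenic, RAG2-deficient B10.A mice, whose receptor recognises a peptide of pigeon cytochrome c. The 1R cells (5 arrays) came from a first transfer into hosts that express this antigen and lack CD3 epsilon, and the 2R cells (8 arrays) from a second transfer of 1R cells into fresh hosts of that kind. Per the labels' protocols, 1R cells were enriched by removing other cell types with antibodies and magnetic beads and sorted as CD4+ TCR+ lineage-negative cells for re-transfer, and RNA was isolated with Trizol and columns, amplified with the Ovation system and labelled with the Agilent ULS kit. The reference was RNA pooled from mouse T cells, and its further composition is not given in the sources used here. All arrays had the same dye orientation, so dye effects could not be averaged out in values against the reference, whereas they cancel in the difference between the groups.

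The deposited table holds 1 signed log2 value per probe and array for 36141 probes, with 0 missing values, and the authors' steps before deposit (scanner software, background correction, normalization and the filter on probes) are not given in the sources used here. Base 2 was inferred from the range of the values, which extended to -11.4, farther than a ratio of whole scanner readings reaches on a log10 or natural log scale. Readings changed by background correction or normalization need not keep to that limit, so the range does not rule out the natural log. Folds given here rest on that base. Array medians lay between -0.034 and 0.046, as they do after centring, and the widths of the distributions differed between arrays, so no scaling to equal width is apparent in the deposited values. Neither the labels nor the table says whether the deposited log2 ratio is sample over reference or its inverse. Directions are therefore given only as higher or lower deposited values, and sizes and distances from 0 do not depend on that choice. All pairs of arrays correlated positively, so the arrays ran the same way round. The probe identifiers are database numbers, and 0 of them matched an identifier of the mouse RefSeq gene table used here. Probes were therefore tested in place of genes. The gene list comparison planned for 31 lists, the check of the ratio's direction with genes outside the sort gate and the settings for genes with several probes need gene names and were not run. All 13 value columns were mapped to samples by their names, and 0 pairs of columns were identical.

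The difference 2R minus 1R was fitted per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) on the deposited values of all 13 arrays, with Benjamini-Hochberg adjustment over 36141 probes and a threshold of 0.05 on the adjusted p. Nothing in the labels says that arrays came from separate animals or transfers, so p-values measure the spread between these arrays, which may in part be technical. The number of arrays limits the precision, and spot intensities and their relation to background are not in the values used here. Spread within groups was compared as the log2 ratio of the mean within-group variance over probes, with a two-sided exact permutation test over all 1287 splits of the arrays into 5 and 8, whose smallest possible p is 0.000777. Distance from the reference was summarised per array as the share of probes at least 2-fold away (an absolute log2 value of 1 or more), at least 4-fold away, and as the SD and interquartile range of the values, each compared with the same exact test. These array summaries were chosen after the data were seen. The other tests between groups, the rule for named probes and the alternatives were set before the data were examined, except for equal SD, the omission of 2R arrays 1 and 2 together and database order as a covariate, which were added afterwards. For unnamed probes the rule names the 2 probes with the largest positive and the 2 with the largest negative difference among those past the threshold.

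The labels number the arrays in a database, and 10 arrays (5 of each group) fall in one run of numbers while 3 arrays, all 2R, fall in a later run. Results were recomputed within the first run and with the run as a block. Repeat numbers 1 to 5 occur in both groups, and the labels do not say that a number is shared. Deviations of same-numbered arrays from their group means correlated between -0.08 and 0.31, so the numbers were not taken as pairs. Alternatives were median centring, quantile normalization, scaling to equal median absolute deviation (MAD) or SD, removal of the 25% of probes with the lowest SD, another variance model, array weights, a test with unequal variances, blocks, other thresholds and leaving out arrays. Settings on missing values were not run because 0 values were missing. The limma step was tested on simulated data for all 36141 probes with the observed spread and 50 changed probes of each size. It recovered 2% of log2 differences of 0.5, 30% of 1, 66% of 2 and 96% of 4, with 9 false calls. Far fewer probes changed in the simulation than differed in the data (2985), which makes the adjusted threshold harder to reach. These shares may therefore understate recovery in the real comparison. The simulated noise was independent between probes and arrays, without the unequal widths of the real arrays.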

Results

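The data comprised 13 arrays, of which 5 measured T cells after a first transfer into antigen-bearing hosts that lack T cells of their own (1R) and 8 measured T cells re-transferred into fresh hosts of the same kind (2R). Each array gave 36141 probes as a log2 ratio between the sample and one reference RNA pooled from mouse T cells. The design asks whether self-reactive T cells that have lived in such a host change their expression after entering another one. Which RNA is the numerator is not given in the sources used here, so positive and negative values do not say which RNA held more of a transcript. Probes carried no gene names, so transcripts are described by probe number and by how far they lay from the reference. Pearson's correlation across probes, which are not independent replicates, ranged from 0.471 to 0.875 over the 78 pairs of arrays. It averaged 0.821 over the 10 pairs within 1R, 0.683 over the 28 pairs within 2R and 0.684 over the 40 pairs that joined the groups.

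**Figure D1:**
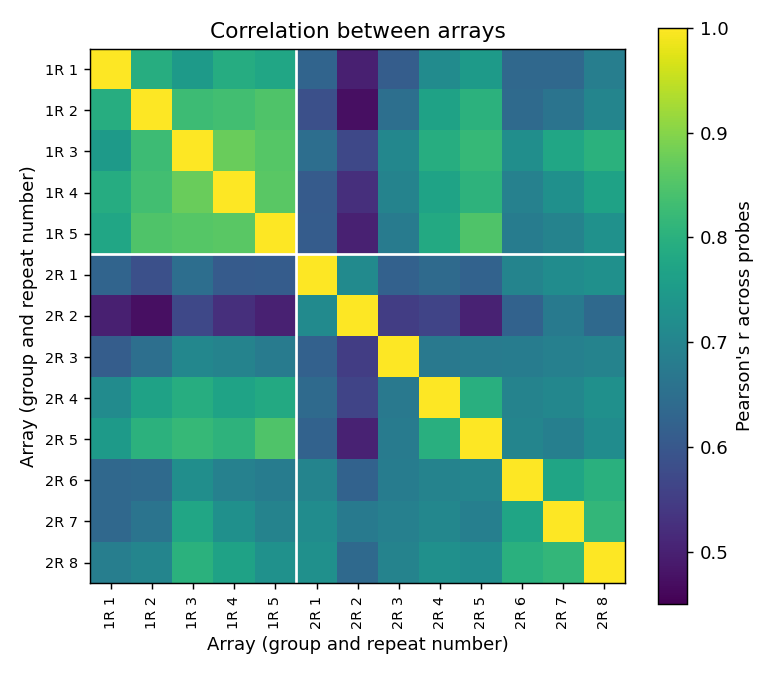
Pearson's correlation across 36141 probes between each pair of the 13 arrays, ordered by group and repeat number, with colour giving r and white lines parting the groups. The 1R arrays form the block with the highest mean correlation (0.821), and 2R arrays 3, 4, 5 and 8 have higher mean correlations with 1R (0.668, 0.765, 0.805 and 0.736) than with the other 2R arrays (0.656, 0.686, 0.673 and 0.731).

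Values of both groups lay away from the pooled reference at a shared set of transcripts. On all 13 arrays, 10331 probes lay on one side of 0, where independent signs would give about 8.82. Signs are not independent here, since all arrays share the reference and the dye orientation, so an excess follows from the design. Of the 10331 probes, 6236 (17.3% of all) had both group means more than 2-fold from the reference, 2402 with positive and 3834 with negative values. At more than 4-fold the asymmetry was larger, with 297 positive and 1579 negative probes. Among the 6236 probes the median absolute group mean was 2.15 in 1R and 1.68 in 2R, and 750 of them also differed between the groups past the threshold used below. The reference was a single RNA pool and dyes were not swapped, so these counts were described and not tested.

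The values of 2R arrays lay nearer to the reference than those of 1R arrays. On 1R arrays 44.2% ± 4.46 (SD, n = 5) of probes were at least 2-fold from the reference, with single arrays between 37.7% and 48.4%. On 2R arrays the share was 31.6% ± 6.15 (SD, n = 8), with single arrays between 22.3% and 39.3%. The difference, 2R minus 1R, was -12.6 percentage points and exceeded the spread between arrays (two-sided exact permutation test over 1287 splits, p = 0.00233; adjusted over the 5 array measures computed, 0.00583). The share of probes at least 4-fold away was 17.3% ± 2.07 in 1R (SD, n = 5) and 10.4% ± 2.31 in 2R (SD, n = 8), with no overlap between the groups (exact permutation p = 0.000777, the smallest this design allows; adjusted, 0.00389). Within the 10 arrays of the first run of database numbers the 2-fold share was 44.2% in 1R and 30.7% in 2R (exact permutation p = 0.0159), while the later run held 3 arrays of 2R only. The 2R arrays 1 and 2 had the narrowest distributions, with 22.5% and 22.3% of probes at least 2-fold away. Without both, the 2R mean was 34.6% ± 2.81 (SD, n = 6; exact permutation p = 0.00649).

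**Figure D2:**
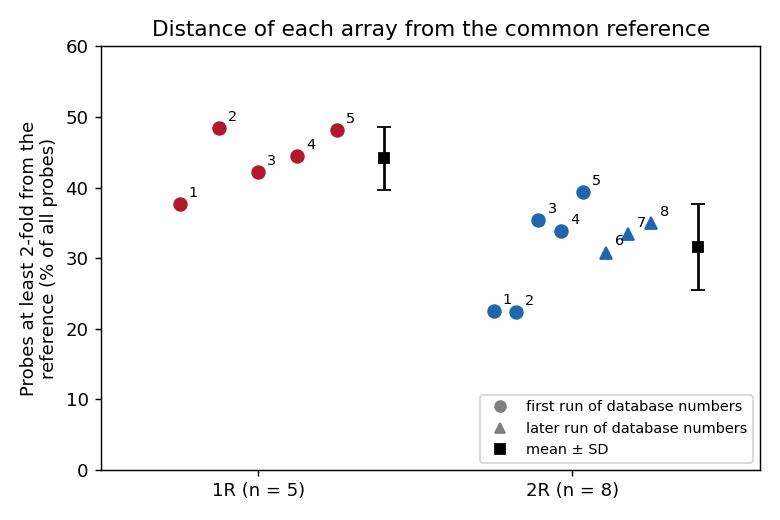
Share of the 36141 probes at least 2-fold from the reference on each array (percent), by group; numbers are repeat numbers, circles mark the first and triangles the later run of database numbers, and squares with bars give the mean and SD. The 1R arrays lie between 37.7% and 48.4% and the 2R arrays between 22.3% and 39.3%.

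Between 2R and 1R, 2985 of 36141 probes (8.26%) differed at the adjusted threshold of 0.05 in limma, 1848 with higher and 1137 with lower deposited values in 2R. The median absolute log2 difference of these probes was 1.21 with a median standard error of 0.284, and 2003 of them differed by more than 2-fold and 292 by more than 4-fold. Most lay nearer to the reference in 2R: 2711 of the 2985 (90.8%) had a 2R mean nearer to 0 than the 1R mean, against 73.2% of all probes, and 274 had a 2R mean farther from 0. Both group means lay on one side of 0 for 2433 of them (81.5%), and 552 had group means on opposite sides. The median absolute group mean of these probes was 1.73 in 1R and 0.645 in 2R. Across all probes the group means correlated at r = 0.875, and the slope of the 2R mean on the 1R mean, which noise in the 1R means lowers, was 0.661. Values of 1R and 2R did not overlap for 1138 probes, where a random split gives about 56.2 (0.155%) on average. Probes vary together, so a single split can give far more, and this number was not compared over splits or at equal width. The count past the threshold, 2985 with the deposited values, was 114 with quantile normalization. Of these 114, 109 were among the 2985, and 50.9% had a deposited 2R mean nearer to 0 than the 1R mean. With equal MAD the count was 0 in limma, with 4786 probes at an unadjusted p under 0.05, against 10021 without scaling. With equal SD it was 138, from 4 without 1R array 4 to 1658 without 2R array 5, and each of the 13 omissions moved it by over 1.5 times. It was 1086 with the run of database numbers as a block, 373 within the first run and 513 without 2R arrays 1 and 2. Leaving out one array left 709 probes without 1R array 2, 851 without 1R array 5, 1189 without 2R array 6, 1297 without 1R array 4, 1495 without 2R array 1, 1651 without 2R array 7, 1664 without 2R array 2 and 4946 without 2R array 5.

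**Figure D3:**
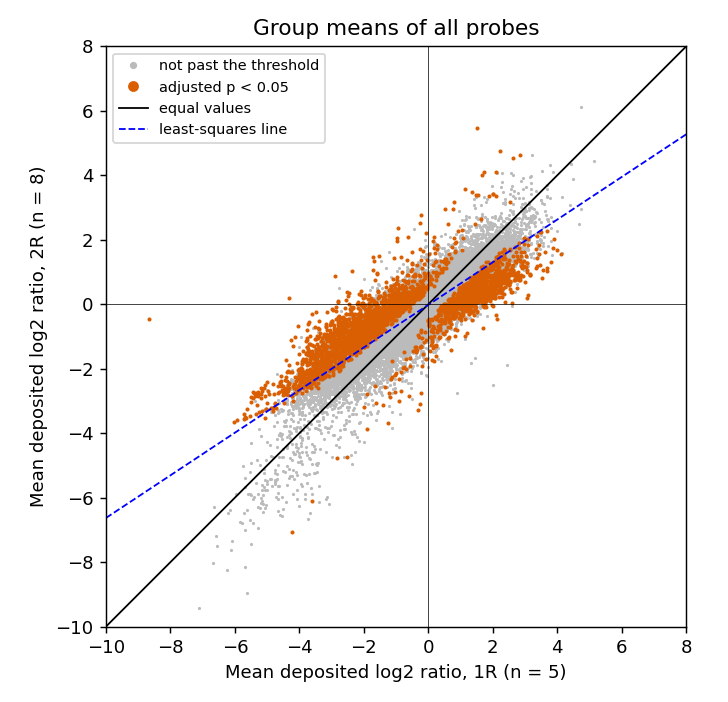
Mean deposited log2 ratio of each probe in 1R (horizontal, n = 5) and 2R (vertical, n = 8); orange points are the 2985 probes past the adjusted threshold of 0.05, the solid line marks equal values and the dashed line is the least-squares fit. Of the orange points, 2711 have a 2R mean nearer to 0 than the 1R mean, and the fitted slope is 0.661.

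The largest difference belonged to a transcript that was far below 0 on every 1R array and near 0 in 2R. Probe 6659555_1 had a mean log2 ratio of -8.65 ± 0.462 in 1R (SD, n = 5) and -0.45 ± 1.32 in 2R (SD, n = 8), a difference of 8.20 with a standard error of 0.576 (limma, adjusted p = 7.94e-05). Its values on 1R arrays 1 and 4, -8.924 and -8.998, were the lowest of all probes on those arrays. Without spot intensities it is unknown whether either channel lay near background there, so the size of 8.20 may not be reliable. Probe 6680207_1 had -4.33 ± 0.514 in 1R and 0.18 ± 1.06 in 2R, a difference of 4.51 with a standard error of 0.48 (limma, adjusted p = 0.00239). In the other direction, probe 6643848_1 had -0.31 ± 1.99 in 1R and -3.27 ± 1.13 in 2R (limma, adjusted p = 0.0395), and its values in the groups overlapped. Probe 6654838_1 had 3.05 ± 0.415 in 1R and 0.20 ± 1.08 in 2R (limma, adjusted p = 0.0118). Over all settings run, the adjusted p ranged from 8.01e-07 to 0.0989 for probe 6659555_1 and from 1.19e-06 to 0.0989 for probe 6680207_1. It ranged from 0.0229 to 0.257 for probe 6643848_1 and from 0.00179 to 0.205 for probe 6654838_1. At equal MAD it was 0.0635 in limma for each of the first pair, whose differences were still 6.42 and 3.93. The 0.0989 came from limma with the replicate block as a fixed term, where their differences were 7.96 and 4.32. Probe 6643848_1 also missed the threshold without any one of 1R arrays 1, 2 and 4 or 2R arrays 1, 2, 6, 7 and 8 (adjusted p up to 0.106 in limma). On 2R array 5, probe 6659555_1 read -2.76, probe 6680207_1 read -2.40 and probe 6654838_1 read 2.32, each the 2R value nearest to the 1R values.

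**Figure D4:**
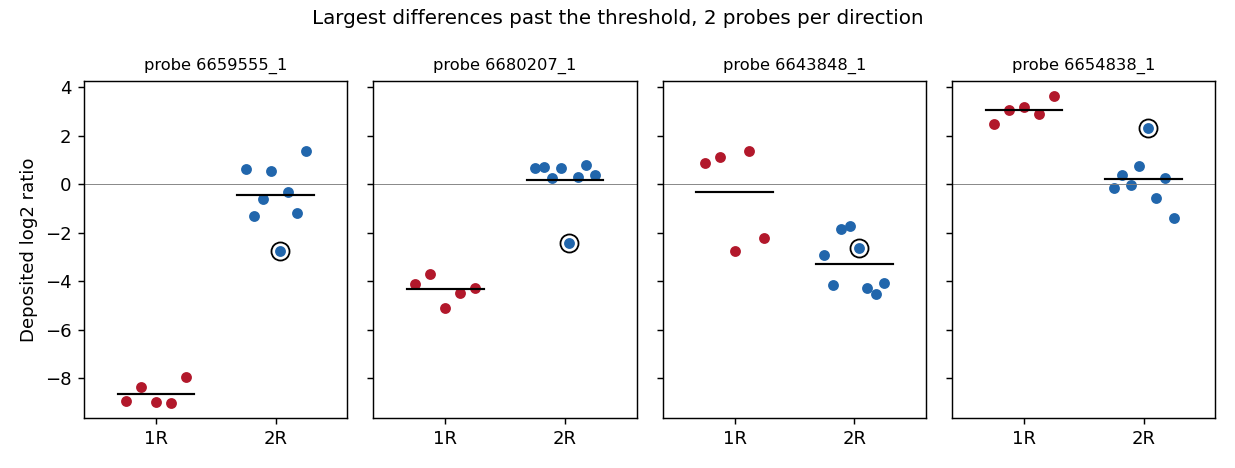
Deposited log2 ratios of the 2 probes with the largest positive and the 2 with the largest negative difference past the threshold, for each 1R array (red, n = 5) and 2R array (blue, n = 8); black lines are group means and the open black circle marks 2R array 5. In probe 6659555_1 the 1R mean is -8.65 and the 2R mean -0.45, and in probes 6659555_1, 6680207_1 and 6654838_1 the circled array is the 2R array nearest to 1R.

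Whether arrays of 2R varied more than arrays of 1R depended on the normalization. With the deposited values the difference missed the threshold: the mean within-group variance over probes was 0.413 in 1R and 0.495 in 2R, a log2 ratio of 0.26 (two-sided exact permutation test over 1287 splits, p = 0.230). Within the first run of database numbers the log2 ratio was 0.37 (exact permutation p = 0.270). After quantile normalization, which gives all arrays one distribution, the log2 ratio was 0.77 (exact permutation p = 0.00466).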

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

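The outlier search and the counts over splits of the arrays with deposited and with quantile-normalized values were planned, and all other tests in this part, those at equal SD included, were chosen after the results were seen. An array was singled out where its gap to the nearest other array of its group was large for the group's range by Dixon's critical value, which chance exceeds in about 1 of 20 groups, or 1.1 of the 22 sets tested here. The 1R array 1 had a mean correlation with the other 1R arrays of 0.777, against 0.826 for the next lowest. For probe 6680207_1, 2R array 5 read -2.40, where the next lowest 2R array read 0.267.

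Most probes that differed between 2R and 1R were nearer to the reference in 2R (2711 of 2985). Of 100 splits of the 13 arrays, 1, the real one, gave as many differing probes, with 1101 in the highest other. This argues against chance assignment of arrays, though the exact 95% interval of that share reached 5.45%. The interval counts the real split, which was always included, as if it had been drawn. Its upper end is therefore somewhat too high, as are those of the other intervals over splits given below. Unequal width of the arrays' distributions stays open: at equal SD 138 probes passed, 134 of them among the 2985, under the 10% set as the limit of the first test, but the limit was passed without 1R array 1 (279 probes at equal SD against 2544 unscaled) and without 2R array 5 (1658 against 4946), and 4 to 208 probes passed at equal SD without any one of the others. The median absolute difference of the 2985 fell from 1.21 (median standard error 0.284) to 0.978 (0.288) at equal SD and 0.776 (0.357) at equal MAD, and tests of width as the whole cause, put in place after the first outcome was known, do not decide: 2 of 100 splits at equal SD gave as many as the 7227 probes at an unadjusted p under 0.05 (highest other 8264) and 4 of 100 at equal MAD as many as 4786 (highest other 8105), with exact 95% intervals that reach 7.04% and 9.93%. The later run of 3 arrays does not alone account for the lower share at least 2-fold away in 2R, which was also lower within the first run (exact permutation p = 0.0159). That test is on the share and does not decide how far the later run adds to the number of differing probes. This number was 373 within the first run, with fewer arrays, and 1086 with the run as a block. One multiplying factor per array is open. The within-group SD of probes near 0, 0.959 times as large in 2R, decides only if both groups vary alike, which is not known. After quantile normalization 2R varied more (log2 variance ratio 0.77), but that step itself widens 2R arrays relative to 1R arrays. Weaker labelled signal and 2R cells that may be nearer in expression to the pooled T cells are open as well.

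After quantile normalization 114 probes differed, of which 50.9% had a deposited 2R mean nearer to 0 than the 1R mean. Of 100 splits, 2 gave as many, the real one included, and since the exact 95% interval of that share reaches 7.04%, chance is not firmly excluded for this count. The other set 2R arrays 2, 3, 6, 7 and 8 against the remaining 8 arrays and gave 394 probes, several times the real count. Those 8 held all 1R arrays and 2R arrays 1, 4 and 5. By mean correlation, 2R arrays 4 and 5 were the nearest to 1R (0.765 and 0.805). By the same measure 2R array 1 (0.616) was farther from 1R than each 2R array of the smaller set except 2R array 2 (0.513). The smaller set held every array of the later run. This split therefore shares part of the contrast between 1R and 2R. Its count cannot tell that contrast from the later run or from another structure among the 2R arrays. With deposited values the same split gave the highest count other than the real one (1101).

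By mean correlation with 1R, 2R arrays 4 and 5 were nearest to that group: with each array left out in turn and placed, over the probes that then differed, between the other 2R arrays (0) and the other 1R arrays (1), the median place was 0.665 for 2R array 5, 0.374 for 2R array 4, at most 0.241 for the other 2R arrays and 0.564 to 0.922 for 1R arrays. At equal SD, over fewer probes, the places were 0.756 for 2R array 5 and 0.407 for 2R array 4, at most 0.264 for the other 2R arrays and 0.139 (1R array 1) to 0.937 for 1R arrays, so the groups' ranges then overlapped more. Labels exchanged between the groups stay open: 0 arrays of 1R had a higher mean correlation with 2R than with the other 1R arrays, but 4 of the 8 arrays of 2R correlated more with 1R, so this test could miss an exchanged array. A wrong label on 2R array 5 alone remains open by its place within the range of 1R, although its values at probes 6659555_1, 6680207_1 and 6654838_1 lay outside that of the 1R arrays, and so do cells that may have changed less, which was not tested. Shared handling remains open as well, since after group means were removed residual correlation fell with distance in database order (Spearman's rho -0.331, one-sided permutation test within groups, p = 0.00099). The resemblance of neighbours was weak, with a mean residual r of 0.046 over 12 adjacent pairs, against -0.106 over the other pairs. The exact permutation tests between groups do not allow for such an order.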

How the results depend on the processing

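The comparison of the 2-fold share, equal SD, the omission of 2R arrays 1 and 2 and the covariate of database order were chosen after the results were seen, and the other settings were planned. The count of 2985 differing probes stayed within 1.5 times under median centring, trend and robust variance estimation, removal of the 25% least variable probes, a random replicate block (3221) and an added 2-fold limit (2003). It became 114 with quantile normalization, 0 with equal MAD (limma; 4786 at an unadjusted p under 0.05), 5326 with array weights, 1583 with unequal variances per probe, 1086 with the run of database numbers as a block, 373 within the first run and 6148 at an adjusted threshold of 0.10. It was 138 with equal SD (4 without 1R array 4 to 1658 without 2R array 5), 513 without 2R arrays 1 and 2, 14 without both and with equal SD, and 550 within the first run with database order as a covariate. Leaving out one array gave 709 (without 1R array 2) to 4946 (without 2R array 5). With the replicate block as a fixed term over repeats 1 to 5, 0 probes passed in limma and 7725 had an unadjusted p under 0.05; that fit uses 10 arrays, as does the unpaired 373. Same-numbered arrays correlated at 0.31, -0.08, -0.03, -0.05 and 0.22 after group means were removed, and 4 of 10 arrays correlated best with their own number. The spread ratio between groups was 0.77 on the log2 scale with quantile normalization (exact permutation p = 0.00466), which widens 2R arrays relative to 1R arrays. It missed the threshold under every other setting run. The 6236 probes on one side of the reference became 1876 with a 4-fold limit and stayed within 1.5 times otherwise. The 2-fold share differed past the threshold under every setting run on it (exact permutation p from 0.00126 to 0.0159); quantile normalization and scalings, which fix widths, were not among them. Of 112 recomputed differences of the 4 named probes, 86 stayed past the threshold, 26 did not and 0 changed sign. Gene lists, the direction check, choices among several probes of a gene and filters on missing values were not run. Fewer arrays entered where arrays were left out; otherwise the cause was not tested. Without intensities, it is unknown which probes lay near background.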
